A study of Rhodococcus jostii with 2 samples.

How the data were processed

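Total RNA from R. jostii RHA1 grown in minimal medium on ferulate or benzoate was treated with DNase and depleted of ribosomal RNA, and Ion Total RNA-Seq libraries were made from it, per the labels' protocols. Each carbon source has 1 culture and 1 library, and the labels name no replicate. The authors deposited raw read counts per locus tag for each library. Bowtie2 2.1.0 and HTSeq 0.5.4 are named in the submitters' processing notes, which give neither their roles nor their parameters in the form used here. The genome build, the annotation, the strand setting and any read filter are not given in the sources used here. Each table has 9212 features (9210 locus tags, tmRNA and RNaseP_bact_a) and 5 tally rows that name no gene. The tally rows were kept out of all totals. They hold 5.54% of the ferulate table's reads and 5.49% of the benzoate table's. The tally of non-unique alignments is 0 in both tables, so how reads from near-identical copies were placed cannot be read from them. Counts of paralogs, and of overlapping or antisense genes, are uncertain for that reason and because the strand setting is not given.

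No reference genome, annotation or table of gene names was used, so tags stand as deposited, without coordinates or products. Of 23 gene lists set before the data were examined, 3 could be used because they were defined by tags. The other 20 depend on gene names or products and were not analysed here. The 3 lists were written from recollection of published work on this strain, not from any table. The benzoate and catechol list holds tags RHA1_ro02373 to RHA1_ro02375 and RHA1_ro02384 to RHA1_ro02388. The vanillin and vanillate list holds RHA1_ro02986, RHA1_ro04164 and RHA1_ro04165. The hydroxycinnamate list holds RHA1_ro05065 to RHA1_ro05080. Shares of reads per replicon were planned and could not be computed without a map of tags to replicons. Runs of neighbouring genes were taken as consecutive tag numbers, which need not be neighbours in the genome or share a strand.

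Counts were scaled with edgeR 4.0.16 (TMM, under R 4.3.3) to effective library sizes, with normalisation factors of 0.881 for ferulate and 1.13 for benzoate. With 1 library per group no test between conditions was made and no p-value is given. The ratio of ferulate to benzoate of each gene carries an exact conditional binomial (Clopper-Pearson) 95% interval. Reads without molecular identifiers are not independent molecules, so these intervals and all limits cover counting error only. Among genes with at least 30 reads and reads in both libraries, the median interval spans a factor of 1.67 to either side of its centre. Where a library had 0 reads, the gene was placed at 3 reads there, and its ratio is given as a bound; this bound is larger, and so less cautious, than the interval limit, which the rule uses. A gene passed the rule when it had at least 30 reads over both libraries and its interval lay wholly above 2 or wholly below 0.5. Shares of reads carry Wilson 95% intervals. The median log2 ratio of a list with at least 3 tags of 30 reads was set beside those of 10000 random lists matched on total reads. Runs were set beside 1000 shuffles. The rule for named genes, set before the data were examined, asked for all members of the main lists, the 12 genes per direction whose interval bound nearest to 1 was farthest from it (the largest interval bound), the longest runs, and up to 4 members of each other list. Because the tags have no names, only the leading 2 tags per direction are printed and the rest are described as groups. The 12 abundant tags, those above 20000 reads, were set apart after the counts were seen. They form 3 classes of 4 tags with similar counts. Their tag numbers fall in near-consecutive sets that each hold a single tag of each class. Repeated ribosomal RNA operons would give both patterns, so the tags may be ribosomal RNA left after depletion. No source used here names them, and this was not tested.

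The calculation was tested on simulated counts for the ferulate against benzoate comparison, drawn from the real means and library sizes with a seeded set of genes changed. At a true fold of 4 the rule recovered 71 of 100 genes, and at 16 it recovered 100 of 100. None of 1743 unchanged genes passed (0%). The interval held the true ratio for 95.8% of 1942 genes. These simulations contain counting error and no variation between cultures. Alternatives covered the scaling (total count, DESeq2 1.42.0 size factors, upper quartile, and total count without the 93 most abundant features, the 1% with most reads), the read minimum, the fold, the interval and the run length. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.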

Results

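The transcriptome of Rhodococcus jostii RHA1, a soil actinobacterium that degrades many aromatic compounds, was sequenced on an Ion PGM instrument after growth on either of 2 aromatic acids. Ferulate is a methoxylated hydroxycinnamate released from plant cell walls and lignin. Benzoate is a simpler aromatic acid that carries no methoxyl group and no side chain. Cells were harvested in mid-exponential phase, and 1 library was made per carbon source, so no value below has a replicate and every interval covers counting error in these 2 libraries only. The ferulate library held 2236276 reads assigned to annotated features and the benzoate library 2328002. Most of them lay on 12 locus tags that each held more than 20000 reads in at least 1 library. The tables do not name these tags. Their tag numbers fall in near-consecutive sets, each with a single tag of each of the 3 count classes described below. Repeated ribosomal RNA operons would give that layout. Whether the tags are ribosomal RNA that outlasted the depletion step was not tested. Those 12 tags took 91.2% of assigned reads on ferulate (Wilson 95% interval 91.1 to 91.2%) and 89.2% on benzoate (89.2 to 89.3%). After these tags and the transfer-messenger RNA were set aside, 167098 reads on ferulate and 222219 on benzoate were left to describe all other genes. Of 9212 features, 2046 had 0 reads in both libraries and 1918 had at least 30 reads over both, the minimum used for the counts of genes below. A count of 0 in a library allows up to 3 reads, or 0.00180% of these remaining reads on ferulate and 0.00135% on benzoate.

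The comparison of the ferulate with the benzoate culture asked which genes were transcribed more on a hydroxycinnamate than on an aromatic acid without the side chain. A set of 51 genes was higher on ferulate and 37 genes were higher on benzoate, each with a 95% interval of its ratio wholly beyond 2-fold. Of the genes with at least 30 reads, 1636 of 1918 (85.3%) had ratios within 2-fold in either direction. The genes higher on ferulate were mostly far apart from the rest: 38 of the 51 differed by at least 16-fold, 41 by at least 8-fold, and 7 by less than 4-fold, with genes at 0 reads in the other library placed at their bound. Among the 37 genes higher on benzoate, 13 differed by at least 16-fold, 18 by at least 8-fold, and 10 by less than 4-fold. The rule itself favours large folds on both sides. In the simulation it recovered 71 of 100 genes at a true fold of 4 and 100 of 100 at 16. With total-count scaling in place of the trimmed mean of M-values (TMM), the numbers were 45 and 62, and the median log2 ratio of genes with at least 30 reads moved from -0.02 to -0.38.

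**Figure D1:**
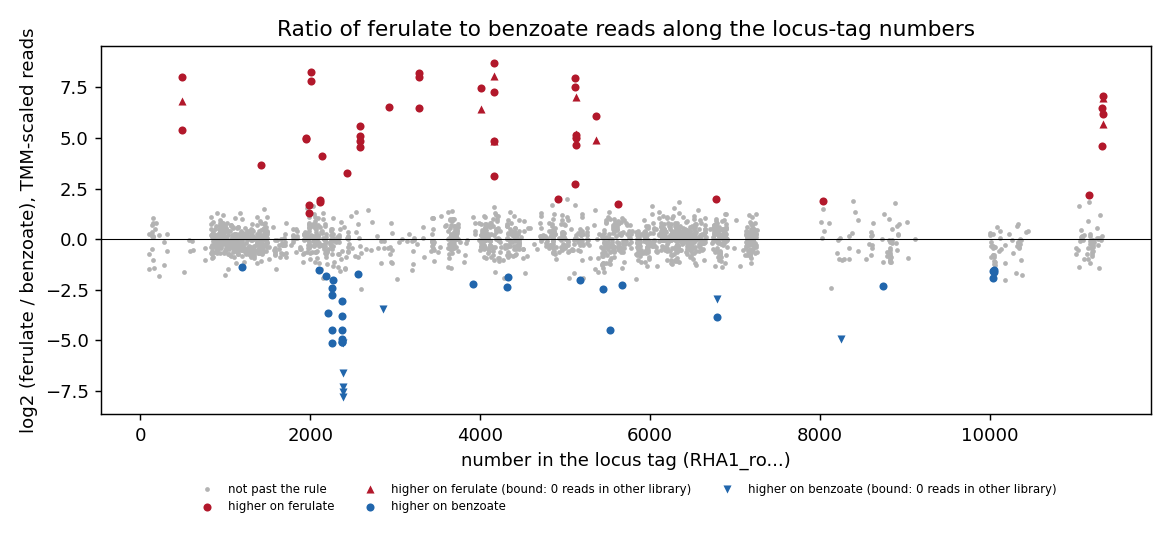
Log2 ratio of TMM-scaled ferulate to benzoate reads (vertical axis) for each locus tag with at least 30 reads, against the number in the tag (horizontal axis). Red and blue points are the 51 genes higher on ferulate and the 37 higher on benzoate, triangles are bounds for genes with 0 reads in the other library, and grey points did not pass the rule; 39 of the 88 coloured points belong to runs of at least 3 consecutive tag numbers.

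The genes higher on ferulate held 11853 reads in the ferulate library and 898 in the benzoate library. They took 7.09% of the reads outside the 12 abundant tags and the transfer-messenger RNA on ferulate, against 0.404% on benzoate; because the genes were picked by this ratio, the contrast describes the set and does not test it. Of these genes, 9 had 0 reads on benzoate and together 1951 on ferulate. The 12 with the largest interval bound had between 194 and 620 reads on ferulate and between 0 and 4 on benzoate, and each was at least 87.2-fold higher on ferulate, by its ratio or its bound. RHA1_ro04165 had 606 reads on ferulate and 0 on benzoate, and its exact 95% interval had the largest lower limit, 220. With 3 reads allowed on benzoate it was at least 271-fold higher on ferulate, or at least 210-fold with total-count scaling. RHA1_ro04163 had 620 reads on ferulate and 2 on benzoate, a ratio of 416 with an exact 95% interval of 115 to 3440. The passing gene with the most reads had 1557 on ferulate and 89 on benzoate, a ratio of 23.5 (exact 95% interval 18.9 to 29.4).

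The genes higher on benzoate held 9234 reads in the benzoate library and 784 in the ferulate library, or 4.16% against 0.469% of the reads outside the abundant features. Of these 37 genes, 8 had 0 reads on ferulate and together 3003 on benzoate. The 12 with the largest interval bound had between 94 and 907 reads on benzoate and between 0 and 22 on ferulate, and each was at least 22.1-fold higher on benzoate, by its ratio or its bound. RHA1_ro02386 had 0 reads on ferulate and 903 on benzoate and was at least 224-fold higher on benzoate. RHA1_ro02384 had 0 and 739 reads and was at least 184-fold higher on benzoate. The locus tags are not paired with gene names in the deposited tables, so other single genes are described by group and not by tag.

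The benzoate and catechol list was set before the data were examined, as tag ranges recalled for the enzymes that oxidise benzoate to catechol and open its ring. Of its 8 tags, 7 had at least 30 reads, and all 7 were higher on benzoate by the rule of 2-fold. The whole list of 8 tags had 24 reads on ferulate and 3750 on benzoate, 117-fold higher on benzoate (exact 95% interval 78.2 to 182). The block of 5 consecutive tags in this list had 0 reads on ferulate and 2804 on benzoate, which took 1.26% of the benzoate reads outside the abundant features. Taken as a block, with 3 reads allowed over the block, it was at least 697-fold higher on benzoate. This bound is less cautious than an exact interval limit. The other 3 tags had 24 reads on ferulate and 946 on benzoate, 29.4-fold higher on benzoate (exact 95% interval 19.6 to 46.1), and the tag in this block that fell short of 30 reads had 3 and 9 reads. The median log2 ratio of the 7 tags was -6.61, or 97.4-fold higher on benzoate, with 5 of the 7 placed at their bound. Under counting error, with these 5 tags held at their bound, this median ran from -6.75 to -6.46. That range holds no error from their 0 reads on ferulate, and adding 0.5 reads to every count gave -9.19. Over all 8 tags the median was -5.85. All 10000 random lists of the same size matched on expression had medians above that of the 7 tags, from -1.41 to 1.2. The random lists drew scattered single tags, whereas this list is a block of 5 and a group of 3 consecutive tags. Neighbouring tags can share their ratios, which the random lists do not allow for. The comparison places the list beyond lists of scattered tags in these libraries and is not a test across cultures. The list's name rests on recollection, because no source used here pairs the tags with products.

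The vanillin and vanillate list, for the enzymes that oxidise vanillin and remove the methyl group of vanillate, had 3 tags recalled in the same way. The whole list had 672 reads on ferulate and 4 on benzoate, a ratio of 225 (exact 95% interval 87.6 to 829). Both tags with at least 30 reads were higher on ferulate. They have consecutive numbers and held 670 reads on ferulate and 0 on benzoate. With 3 reads allowed on benzoate, the pair was at least 299-fold higher on ferulate. RHA1_ro04165 belongs to the pair, and the other tag of the pair had 64 reads on ferulate. The remaining tag was barely detected, with 2 reads on ferulate and 4 on benzoate, which leaves its direction open (ratio 0.67, exact 95% interval 0.061 to 4.68). The hydroxycinnamate list was a range of 16 tags recalled as the neighbourhood of the genes for hydroxycinnamate side-chain removal. None of its tags passed the rule, and only 1 had at least 30 reads (21 on ferulate and 20 on benzoate). Of the tags under 30 reads, 1 had 10 reads on ferulate and 2 on benzoate (ratio 6.71, exact 95% interval 1.43 to 62.9). No other interval in the range left out 1. The range as a whole had 72 reads on ferulate and 78 on benzoate. Its summed ratio was 1.24 with an exact 95% interval of 0.886 to 1.73. No table used here checks whether any of the 3 lists holds the genes it was named for, and this holds alike for the 2 lists whose tags passed the rule and for this range, whose tags did not.

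**Figure D2:**
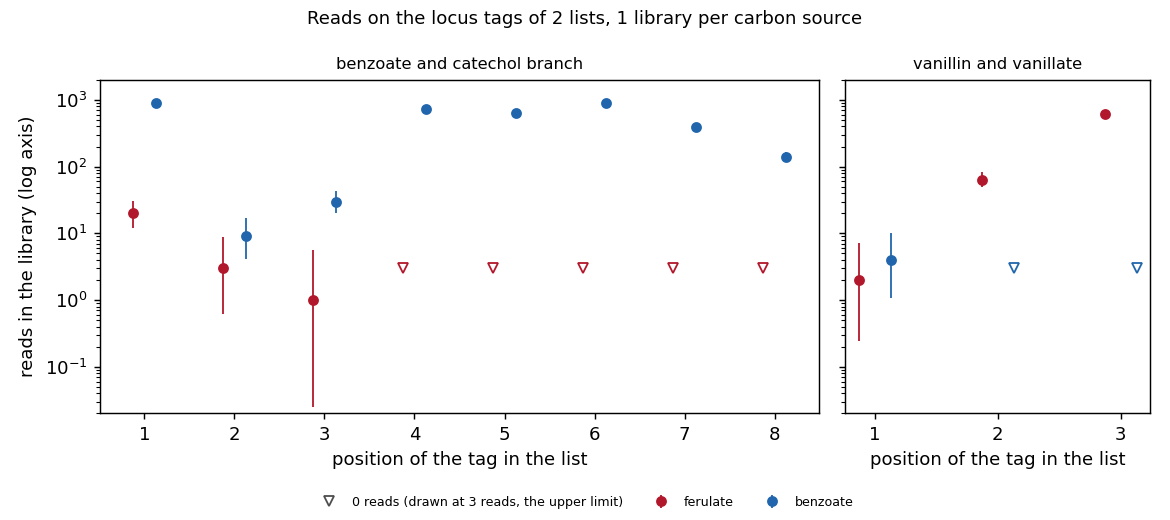
Reads per library (vertical log axis) for each tag, in tag order (horizontal axis), of the benzoate and catechol list and the vanillin and vanillate list; red is ferulate, blue is benzoate, bars are exact 95% Poisson intervals for counting error, and open triangles mark 0 reads drawn at the limit of 3. Positions 4 to 8 of the benzoate and catechol list had 0 reads on ferulate, and positions 2 and 3 of the vanillin and vanillate list had 0 reads on benzoate.

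Of the 88 genes past the rule, 39 lay in runs of at least 3 consecutive tag numbers. There were 10 such runs, 6 higher on ferulate with 24 genes and 4 higher on benzoate with 15 genes. Runs hold only genes that had passed the rule on their own ratio, so the pooled ratios and intervals of the runs describe the picked genes and test nothing further. The longest run on the ferulate side had 6 tags, with 1106 reads on ferulate and 13 on benzoate (ratio 114, exact 95% interval 66.4 to 215). A run of 4 tags with 2553 reads on ferulate and 129 on benzoate had the most reads of any ferulate run (ratio 26.5, interval 22.2 to 31.9). The run that includes the vanillate pair had 4 tags, with 1634 and 5 reads (ratio 438, interval 187 to 1352). A further run of 4 tags had 1075 reads on ferulate and 7 on benzoate (ratio 206, interval 99.6 to 513). The remaining ferulate runs had 3 tags each, with 633 and 7 reads in one and 430 and 15 in the other. On the benzoate side the longest run was the 5-tag block of the benzoate and catechol list. A run of 3 tags that shares 1 tag with that list had 57 reads on ferulate and 2471 on benzoate, 32.3-fold higher on benzoate (interval 24.9 to 42.8). A run of 4 tags had 24 and 413 reads, 12.8-fold higher on benzoate (interval 8.5 to 20.3). The last had 174 and 723 reads on 3 tags and was 3.10-fold higher on benzoate (interval 2.62 to 3.68). In 1000 shuffles of the passing genes over all locus tags, no shuffle gave more than 1 run. Of the 10 runs, 7 shared no tag with any list, 5 on the ferulate side and 2 on the benzoate side.

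Only 2 features carry a name in the tables, and both are structural RNAs. The transfer-messenger RNA (tmRNA), which frees stalled ribosomes, had 30509 reads on ferulate and 28714 on benzoate, a TMM-scaled ratio of 1.42 (exact 95% interval 1.40 to 1.45). The RNA of ribonuclease P (RNaseP_bact_a), which trims the 5′ ends of transfer RNA precursors, had 1694 and 2833 reads, a ratio of 0.80 (interval 0.75 to 0.85). Neither passed the rule of 2-fold. With total-count scaling the ratios were 1.11 for tmRNA and 0.62 for RNaseP_bact_a, so each kept its side of 1, while these intervals hold no variation between cultures.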

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

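Reads outside annotated features were not used in any comparison and stood far above the limit of 3 reads that a count of 0 allows. The tally of reads lying in no feature was 49477 on ferulate and 57810 on benzoate. These equal 2.09% of all reads in the ferulate table and 2.35% in the benzoate table. Set against reads on genes outside the 12 abundant tags and tmRNA, they equal 29.6 per 100 on ferulate and 26.0 on benzoate. The direction thus depends on the base, and how many of them arose near the 12 abundant tags is unknown. Reads tallied as ambiguous, falling on more than a single feature, numbered 6368 on ferulate and 8229 on benzoate, or 0.269% and 0.334% of all reads in each table. Reads tallied as not aligned numbered 75279 on ferulate (3.18%) and 69136 on benzoate (2.81%). The tables give no positions for these reads. No sample could be compared with others of its group, and no effect could be compared between groups, since each group has 1 library.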

How the results depend on the processing

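The benzoate thinning (to the ferulate depth outside the 12 abundant tags), the total without the 12 abundant tags and the 0.5-read alternative were chosen after seeing the data. Counts of passing genes were 51 on ferulate and 37 on benzoate. Total-count scaling gave 62 genes higher on benzoate, among them all 37, and 45 higher on ferulate, all among the 51. A minimum of 100 reads left 23 higher on benzoate and 36 on ferulate, and asking for an interval beyond 4-fold left 15, against 41 on ferulate. An interval beyond 1.5-fold gave 80 on ferulate and 67 on benzoate. The point ratio alone, beyond 2-fold with no interval, gave 139 and 143, so the excess on the ferulate side was not kept there. The other settings stayed within 1.5 times, from 48 to 70 genes on ferulate and from 28 to 52 on benzoate. The median of the benzoate and catechol list (log2 ratio -6.61) stayed negative throughout. It was -6.97 with total-count scaling, -5.85 with a minimum of 10 reads or none, -6.95 with 100 reads, and -9.19 when 0.5 reads were added to every count in place of the 3-read bound. The 10 runs became 18 when pairs of tags counted and 6 when 4 tags were required, by construction. Of 24 recomputed ratios of 6 single features, none reversed and 6 moved beyond their counting interval, 4 of them for tmRNA. The DESeq2 and upper-quartile settings gave equal factors here and so are not separate checks. The replicon shares and the list without product matches were not run, for lack of annotation, and the 1% setting could not leave out ribosomal and transfer RNA by name. No paired analysis was possible because each group has 1 library. Depth limits the view to 1918 of 9212 features, and no setting can stand in for replicate cultures.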

Other observations

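The tests on the abundant tags and on carry-over between libraries were chosen after the result was seen; the thinning and shuffle tests were set before their results were seen, though after the counts. The 12 abundant tags fell into 3 classes of 4 tags with similar counts. By tag number they fell into near-consecutive sets, each with a single tag of each class. The 4 largest had between 392484 and 404141 reads on ferulate and between 401892 and 412523 on benzoate. The middle 4 had 66115 to 83604 reads on ferulate and 73269 to 93390 on benzoate. The smallest 4 had 36055 to 37094 reads on ferulate and 28122 to 28723 on benzoate. As shares of assigned reads the classes differed in direction between libraries, whereas with TMM scaling all 3 were higher on ferulate (ratios 1.31, 1.20 and 1.73 from the largest class to the smallest): the largest took 71.2% on ferulate and 70.0% on benzoate, the middle 13.4% and 14.4%, and the smallest 6.55% and 4.88%. The share of the smallest class was 1.34 times as large on ferulate, and all 4 of its tags had more reads there. If these tags are near-identical copies, their 4 counts need not be separate measurements, because how such reads were placed is unknown.

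Under TMM scaling 88 genes passed the rule and 58.0% of them were higher on ferulate. Under total-count scaling a larger set of 107 genes passed, 42.1% of them higher on ferulate; it held all 37 benzoate genes and 45 of the 51 ferulate genes of the TMM set on their former side. With the 12 abundant tags left out of the total, 89 genes passed and the figure was 56.2%, within 5 points of the TMM value. The planned total without the 93 most abundant features, which include these 12, also gave 56.2%, so this was not a fresh test. The values show that the total-count split depends on a few abundant rows, and not which scaling is right. The deeper benzoate library was thinned 100 times to 78.7% of its reads. This matches the ferulate depth outside the 12 abundant tags and not the total depth. The median share of genes higher on ferulate was 61.7% (57.5 to 65.0%), a move of less than the 10 points set as the limit. That limit is wider than the gap between 58.0% and an even split, so the limit itself could not decide whether depth made the gap. Every thinning kept more genes on the ferulate side. The thinned sets had 27 to 37 genes higher on benzoate and 48 to 54 higher on ferulate. These values argue against the depth difference as the source of the gap in these libraries. The abundant tags took 1.94 percentage points more of the assigned reads on ferulate. Whether that came from the carbon source or from the making of the libraries cannot be told apart with 1 library each.

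Some genes past the rule kept reads in the opposite library, and carry-over of reads between the libraries is a candidate explanation. The 5-tag block of the benzoate and catechol list, with 2804 reads on benzoate and 0 on ferulate, limits such carry-over into the ferulate library to 0.107% of the benzoate reads. The run of 3 tags that shares 1 tag with that list kept 2.31% (exact 95% interval 1.7 to 3.0%), which is above the limit, so carry-over alone does not account for it. A low transcript level on ferulate stays open as a hypothesis, as do reads from similar genes elsewhere, which the tables cannot separate.

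For the runs, chance placement among expressed genes was tested by shuffling the passing genes over the tags with at least 30 reads. As many as 10 runs appeared in 0 of 1000 shuffles, and no shuffle gave more than 1 run. Co-transcription of neighbouring genes may explain the runs and was not tested, because neither strand nor position was used. Of the 88 passing genes, 79 lay outside the lists, and 5 of the 6 ferulate runs shared no tag with them.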
